A study of Mus musculus with 104 samples.

How the data were processed

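RNA drawn from single mouse substantia nigra neurons into patch pipettes was converted to full-length cDNA by the Smart-seq2 protocol, and libraries were made with the HyperPlus kit, per the labels' protocols. The authors deposited a single table of counts, whole reads per gene symbol, for 104 libraries. STAR 2.5.3a, featureCounts 1.5.3 and the mouse build mm10 are named in the submitters' processing notes, without their role or order. The gene annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The table held 45808 gene rows and 92 rows of ERCC spike-ins, which were kept out of library totals. No row for EGFP or another reporter was used here.

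Groups were read from the sample titles, 38 experiment and 66 control. The libraries were also divided into 2 sets, called title sets, which the labels do not call batches. Control titles change letter case after number 37, and the records list experiment 36 and above as 1 block with the lower-case controls. Experiment titles show no such change, so their division rests on the order of the records. Set 1 held 21 experiment and 31 control libraries and set 2 17 and 35. Values within each set are given because the sets differed in depth and in the share of mitochondrial counts. The sets held different shares of each group, so a pooled ratio can lie outside the ratios of both sets. Within set 1, controls 1 to 10 were deeper than controls 15 to 37 and mostly lower in that share. These blocks were not analysed apart. The labels tie no library to an animal, so each group counted as 1 sample and no p-value, standard error or number of changed genes was computed. Libraries needed 50000 gene counts and 1000 genes with a count, and 0 were left out. No pair of the 5356 pairs of libraries had identical counts, and every library was kept. Whether libraries with similar counts share RNA was not settled.

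The counts deposited by the authors were summed per gene over the libraries of a group and divided by the group's summed gene counts, giving a pooled CPM (counts scaled to a common total) with an exact Poisson 95% interval. The ratio of pooled CPM, experiment over control, carries the interval of the exact binomial split of the summed counts. Reads carry no molecular identifiers and neurons differ from each other, so these intervals cover counting error only and are far narrower than the spread between neurons. For ratios, a group sum below 3 counts was raised to 3. Beside the pooled value stand the mean of the library CPM, which weights libraries equally, and the quartiles over libraries. For shares of libraries with a count, each library was thinned to 400000 counts, and 4 experiment and 6 control libraries below that depth were left out.

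A gene was expressed if its pooled CPM over all libraries was at least 10 and at least 25% of the libraries of a group had a count, which held for 9113 genes. The median log2 ratio of all expressed genes was -0.03 by pooled CPM and -0.02 by the equally weighted mean. It was -0.38 for the difference of mean log2(CPM + 1), so values on that scale are read relative to this shift.

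Before the data were examined, 27 gene lists were fixed, together with the processing alternatives. They cover dopaminergic identity, the ventral tier, the ventral tegmental area and dorsal tier, the proteasome, cytosolic chaperones, endoplasmic reticulum and integrated stress, autophagy and lysosome, nuclear-encoded and mitochondrial-encoded respiratory genes, and glycolysis. Others cover NRF2 targets, synaptic vesicles, the axon cytoskeleton, ion channels, ribosomal proteins, immediate early genes, p53 and apoptosis, axon injury, interferon and class I genes, and Parkinson disease genes. The rest hold markers of GABAergic neurons, astrocytes, microglia, oligodendrocytes and their precursors, endothelial and mural cells, and blood cells. Each list is described by the median log2 ratio of its expressed genes, a 95% interval from order statistics over those genes (the full range for lists under 6 genes), and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is not a test between conditions.

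Genes were named by a rule of size fixed at the same time. It took expressed genes at least 1.5-fold apart in the same direction by both weightings, with the thinned share of libraries and the pooled ratio of both title sets in that direction. Unnamed gene models, pseudogenes, ribosomal protein, mitochondrial, haemoglobin and sex-linked marker genes were left out. Genes were ranked by the smaller of the 2 absolute log2 ratios, and the 12 highest and 12 lowest were taken. Th, Slc6a3, Slc18a2 and Ddc were named whatever their values, as were up to 4 expressed genes per list by the same ranking, whether or not they met the rest of the rule. Results for some genes are not reported here. Genomic positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names.

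The procedure was tested on simulated counts for the 9113 expressed genes, drawn with the control means, detection shares, spread and the real library sizes, with 200 genes altered in the experiment group. Doubled genes were recovered at a median log2 ratio of 0.94 and genes raised 4 times at 1.93 (50 genes each), and genes set to a ratio of 0.5 or 0.25 at -1.11 and -1.98. Among the 8913 unaltered genes, 10.5% passed 1.5-fold by both weightings. Genes and libraries were drawn independently, without differences between title sets, animals or the RNA yield of the groups. The interval of the list medians was checked apart from these counts, on simulated normal values. It was at first too narrow by an error of indexing, and it was corrected before the values given here were computed.

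Alternatives fixed in advance were equal weights, mean log2(CPM + 1), each title set alone, no library filter, at least 200000 counts and 3000 genes, leaving out the deepest library of each group, leaving out libraries above the 90th percentile of glial marker CPM, and keeping libraries with Th and another dopaminergic marker. TMM factors, totals without mitochondrial genes and the 20 highest genes, and looser and stricter expression filters were also fixed in advance. Further alternatives, chosen after seeing the data, are named where their values are given. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.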

Results

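Patch pipettes were used to draw the content of single neurons from slices of mouse substantia nigra, the midbrain region whose dopaminergic neurons are lost in Parkinson disease. The series concerns fluorescent reporters of Lewy pathology, the protein inclusions of that disease, and its design text describes the collection of neurons that carried fluorescent inclusions. Every library is labelled as a dopaminergic neuron. The titles divide the 104 libraries into 38 named experiment and 66 named control, and the labels used here do not say which neurons served as control. The comparison therefore asks how the transcripts of the neurons titled experiment differed from those titled control.

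Each library is the content of a single pipette, and the labels name no animal. Each group was therefore treated as 1 sample, no test between groups was made, and every interval on a level or ratio below covers counting error only. Spread across libraries is given as quartiles, as a description of these libraries.

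Experiment libraries held 116567 to 3094036 gene counts (median 960027) and control libraries 153770 to 2577694 (median 1039850). A median of 7354 genes had a count in experiment libraries and 8548 in control libraries. After thinning to 400000 counts, which left out 4 experiment and 6 control libraries, the medians were 6916 and 8460 genes. ERCC spike-ins, synthetic RNAs added with the lysis buffer, took a median of 0.421% of the counts in experiment libraries and 0.251% in control libraries. Genes encoded by the mitochondrial genome took a median of 4.33% and 2.72% of the gene counts.

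**Figure D1:**
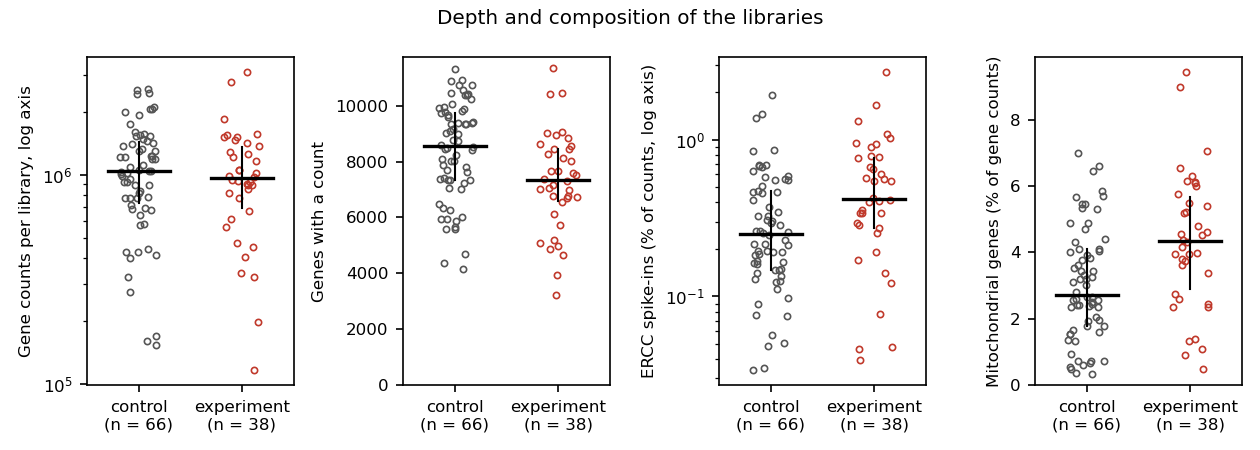
Gene counts, genes with a count, share of ERCC spike-in counts and share of mitochondrial gene counts in each library (1 circle per library; 66 control and 38 experiment). Thick lines are medians and thin lines span the quartiles. Experiment libraries had fewer genes with a count (median 7354 against 8548) and a higher ERCC share (median 0.421% against 0.251%).

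Transcripts that define the dopaminergic neuron were lower in the experiment libraries. Th, which encodes the rate-limiting enzyme of dopamine synthesis (mouse GRCm38, chromosome 7, 142892752 to 142931128, minus strand), stood at 5277 CPM (counts scaled to a common library total; interval 5254 to 5299) against 9726 (9703 to 9748) in control, a ratio of 0.543 (0.540 to 0.545). Th lay below the control median in 36 of the 38 experiment libraries, and its quartiles were 3644 and 7069 CPM against 6616 and 11968. Of the 23 expressed genes of the dopaminergic identity list, 18 were lower and 2 higher by both the pooled and the equally weighted CPM. The median log2 ratio of the list was -0.38 (95% interval over its genes -0.88 to -0.24), at percentile 0.03 among 10000 random lists matched on expression.

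The size of the difference varied among these genes. Dlk1, a Notch-family ligand of midbrain dopaminergic neurons, stood at 414 against 899 CPM and lay below the control median in 35 experiment libraries. Gch1, which makes the cofactor of tyrosine hydroxylase, had a ratio of 0.497, Gfra1, a GDNF co-receptor, 0.286, Foxa2, a dopaminergic transcription factor, 0.427, and Maob, which degrades dopamine, 0.272. Foxa2 was lower in title set 2 (log2 ratio -3.21) and not in title set 1 (0.23), the 2 sets of libraries described next. The dopamine transporter Slc6a3 (chromosome 13, 73536747 to 73578672, plus strand) had a ratio of 0.800 (0.795 to 0.806), the vesicular transporter Slc18a2 0.847 and the decarboxylase Ddc 0.816.

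The libraries were divided into 2 sets by the letter case of control titles, which changes after number 37, and by the order of the records, which lists experiment 36 and above together with the later controls. This gave 21 experiment and 31 control libraries in set 1 and 17 and 35 in set 2. The ratio of Th was 0.609 in set 1 and 0.540 in set 2, while that of Slc6a3 was 1.02 and 0.719 and that of Slc18a2 1.13 and 0.662. The dopaminergic list had a median of -0.20 in set 1, -0.43 in set 2 and -0.23 without the libraries highest in glial markers.

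**Figure D2:**
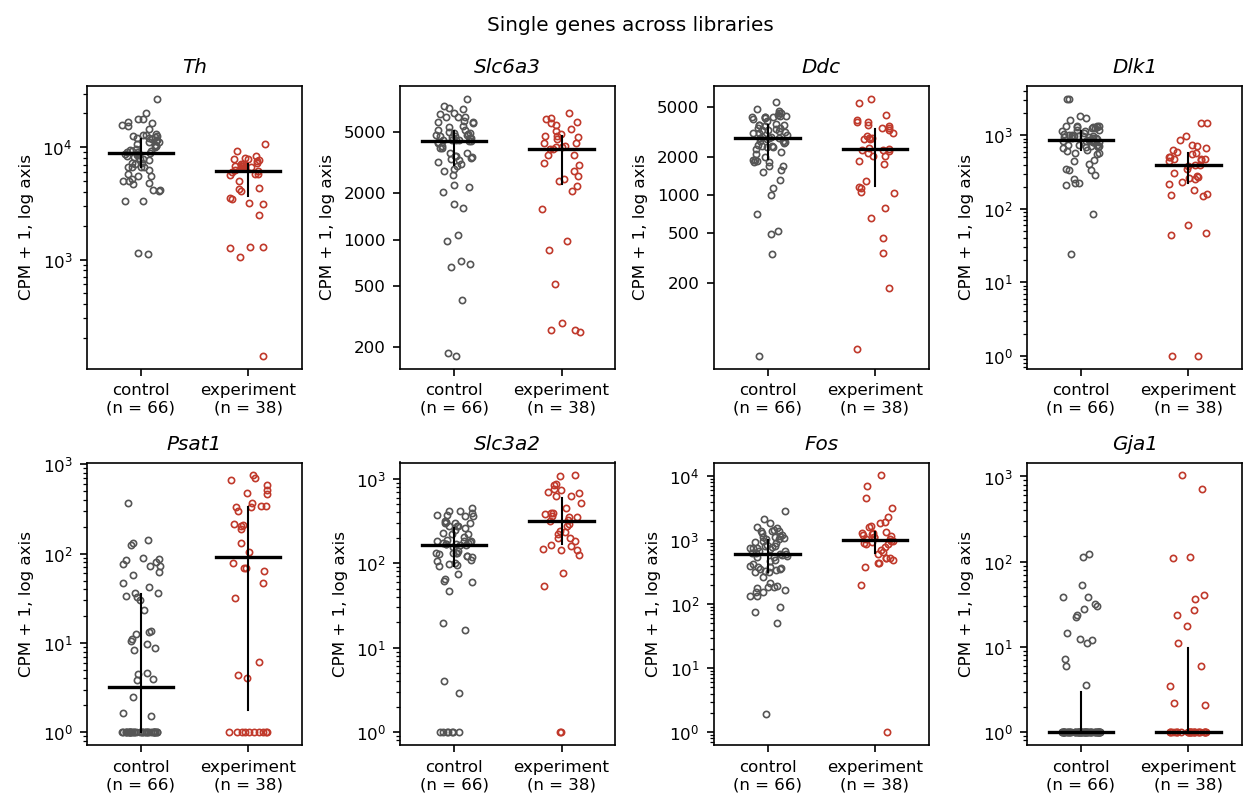
CPM + 1 of 8 genes in each library on a log axis (1 circle per library; 66 control and 38 experiment), with medians (thick lines) and quartiles (thin lines). Th and Dlk1 sit lower in experiment libraries, Slc6a3 and Ddc overlap in both groups, and Psat1, Slc3a2 and Fos sit higher. Gja1 is at 0 in most libraries of both groups and reaches its highest values in a few experiment libraries.

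Markers of dopaminergic subtypes also differed. Calb1, a calcium-binding protein of dorsal-tier and ventral tegmental neurons, stood at 89.7 against 552 CPM, and Tacr3, the neurokinin 3 receptor, at 12.02 against 95.9 CPM. Tacr3 belongs to both subtype lists. All 7 expressed genes of the ventral tegmental and dorsal-tier list were lower by both weightings, with a median log2 ratio of -0.79 (-3.00 to -0.23, percentile 0.05). The median of this list was -1.77 in title set 1, -1.04 in title set 2 and -1.71 without the highest library of each group for each gene. Adcyap1 and Neurod6 were nevertheless higher in title set 2 (log2 ratios 3.18 and 4.97). The ventral-tier list held 4 lower and 2 higher genes out of 8, with a median of -0.28 (-3.00 to 2.60, percentile 4.45). Its median was -0.09 with equal weights (percentile 25.9), 0.23 in title set 1 and -0.34 in title set 2, so no direction is given for this list as a whole. Its higher members were Anxa1, at 164 against 27.1 CPM, and Aldh1a1, which oxidises dopamine-derived and retinoid aldehydes, at 1568 against 710 CPM. The ratio of Aldh1a1 was above 1 in title set 2 only, with log2 ratios of -0.19 in set 1 and 2.39 in set 2.

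Synaptic vesicle and lysosomal transcripts were modestly lower by pooled and equally weighted CPM, but not relative to other genes by mean log2(CPM + 1), where the lists stood at -0.31 and -0.29 against -0.38 for all expressed genes. In the synaptic vesicle list 30 of 43 expressed genes were lower and 8 higher, with a median log2 ratio of -0.26 (-0.31 to -0.08, percentile 0.06). Among them, the vesicle GTPases Rab3b and Rab3c had ratios of 0.451 and 0.659, the vesicle glycoprotein Sv2b 0.703, and the endocytic GTPase Dnm1 0.720. In the autophagy and lysosome list 30 of 50 genes were lower and 11 higher, with a median of -0.21 (-0.27 to -0.03, percentile 0.55). Atp13a2, a lysosomal polyamine transporter mutated in a juvenile parkinsonism, had a ratio of 0.521 and Tmem175, a lysosomal potassium channel, 0.484. Npc1 and Cd63 stood higher, with ratios of 2.38 and 1.80, although Cd63 was lower in title set 2 (log2 ratio -0.26) and Npc1 in libraries low in ERCC share (-0.18), those at or below the overall median, a split chosen after seeing the data. The lysosomal median was -0.03 in title set 1, where that of all expressed genes was -0.10, and -0.23 in title set 2. The synaptic vesicle median was -0.13 and -0.37. The Parkinson disease gene list, which includes Gch1, Atp13a2, Tmem175 and Vps13c (ratio 0.564), had a median of -0.13 (-0.41 to 0.07, percentile 15.5), with 16 of 24 genes lower.

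Ribosomal protein and respiratory chain transcripts were higher. All 76 expressed ribosomal protein genes were higher by both weightings, with a median log2 ratio of 0.52 (0.47 to 0.58, percentile 100), and Rps29, Rps19, Rps23 and Rps27 had ratios of 1.98, 1.97, 1.96 and 1.74. The ribosomal median was 0.34 with equal weights, 0.26 by mean log2(CPM + 1), 0.40 in title set 1, 0.66 in title set 2 and 0.41 without the highest library of each group for each gene. Of 75 nuclear-encoded respiratory chain genes, 54 were higher and 10 lower, with a median of 0.20 (0.14 to 0.24, percentile 100). Ndufb9 and Atp5g2 had ratios of 1.45 and 1.58, Uqcrq 1.32 and Ndufs1 0.697. All 9 expressed mitochondrial-encoded genes were higher, with a median of 0.56 (0.32 to 0.74, percentile 99.98), led by mt-Nd3 with a ratio of 2.49. Ribosomal protein genes have many processed pseudogenes, and how reads that fit several places were counted is not given in the sources used here, so their levels are uncertain. The mitochondrial median was 1.21 in title set 1, 0.50 in title set 2 and 0.16 among the libraries low in ERCC share.

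Activity-dependent and stress genes differed in part. In the immediate early gene list 18 of 25 expressed genes were higher and 3 lower, with a median of 0.54 (0.34 to 0.80, percentile 100). Fos stood at 1540 against 779 CPM and above the control median in 29 of 38 experiment libraries, Nr4a1 had a ratio of 1.91 but was lower in libraries low in ERCC share (log2 ratio -0.71), and the MAP kinase phosphatase Dusp6 3.32. With equal weights Dusp6 had a ratio of 1.99, and after thinning it had a count in 10 of 34 experiment and 25 of 60 control libraries. The median of this list was 0.20 without the libraries highest in glial markers, 0.44 in title set 1 and 0.21 in title set 2. The list of endoplasmic reticulum and integrated stress response genes divided evenly, with 14 of 30 higher and 14 lower, a median of 0.13 (-0.31 to 0.59) and percentile 96.0. The 4 members ranked first by the smaller of the pooled and equally weighted log2 ratios were all higher: Psat1 and Phgdh, enzymes of serine synthesis, had ratios of 6.08 (5.80 to 6.37) and 5.41 (5.05 to 5.79), the amino acid transporter Slc7a5 4.17, and the glutathione-degrading Chac1 2.79. Psat1 (chromosome 19, 15904678 to 15947337, minus strand) was above the control median in 28 experiment libraries. Its ratio was 2.60 in title set 1 and 10.1 in title set 2, that of Phgdh 1.88 and 10.2, that of Slc7a5 1.10 and 7.06, and that of Chac1 1.63 and 4.02. Chac1 was above the control median in 19 of 38 experiment libraries, and after thinning Slc7a5 and Chac1 had a count in 22 and 18 of 34 experiment libraries against 41 and 37 of 60 control libraries. With each library weighted equally, the stress list had a median of -0.04, with percentile 38.7.

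Protein quality control lists stood close to level. The proteasome list had a median of 0.07 (-0.05 to 0.30, percentile 91.1), with 22 of 36 genes higher and 10 lower. Psmc2, an ATPase subunit, had a ratio of 1.55, and the activator Psme4 0.475. The cytosolic chaperone list had a median of 0.07 (-0.08 to 0.22, percentile 92.4), with 20 of 33 genes higher and 10 lower. Within it, the small heat shock proteins Cryab and Hspb8 had ratios of 1.84 and 1.94, and Hspa4l 0.593. Cryab was lower in title set 2 (log2 ratio -1.30) and Hspb8 slightly lower in title set 1 (-0.10).

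Astrocyte markers, and most microglial and GABAergic markers, were higher in experiment libraries by pooled and equally weighted CPM. All 11 expressed astrocyte markers were higher, with a median log2 ratio of 1.47 (0.44 to 2.56, percentile 100). The angiotensinogen gene Agt stood at 99.2 against 15.3 CPM and the gap junction gene Gja1 at 59.1 against 10.02 CPM. Experiment library 27 alone held 49.4% of the Agt counts and 54.3% of the Gja1 counts of its group, and the ratios without the highest library of each group were 4.46 and 4.44. Gja1 was lower without the libraries highest in glial markers (log2 ratio -0.26), and in libraries low in ERCC share Gja1, Agt and Ctss were lower (-1.17, -0.57 and -0.063). Of 8 microglial markers 7 were higher, with a median of 0.80 (-0.53 to 1.28, percentile 100), including Ctss with a ratio of 2.43 and C1qb with 2.32. The oligodendrocyte list had a median of 0.23 (-1.14 to 1.41, percentile 92.8), and its myelin genes Mobp and Mbp had pooled ratios of 2.65 and 1.79. By mean log2(CPM + 1) they stood at -0.18 and -0.72, and Mobp was above the control median in 18 of 38 experiment libraries, with a count after thinning in 23 of 34 experiment and 49 of 60 control libraries. In title set 2 alone the oligodendrocyte median was -2.17. GABAergic markers were higher for 4 of 5 genes, with a median of 1.53 (range -0.15 to 3.09) and percentile 100. Among these, Gata3, Gad1 and Pvalb had ratios of 8.49, 3.35 and 2.89. Gad2 was lower in title set 1 (log2 ratio -0.52). Summed GABAergic marker CPM had a median of 433 per experiment library and 398 per control library in title set 1. In title set 2 these medians were 192 and 190. For microglial markers they were 185 and 69.2 in title set 1 and 215 and 248 in title set 2.

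The summed CPM of astrocyte, microglial and oligodendrocyte markers had a median of 2222 per experiment library and 1210 per control library. The astrocyte median was 0.29 without the libraries highest in glial markers and -0.27 among the libraries low in ERCC share. In the oligodendrocyte precursor list 2 genes were expressed, Lhfpl3 with a ratio of 0.286 and Olig1 with 1.35. No endothelial or blood cell marker passed the expression filter, and their summed CPM were 3.63 and 20.9 in experiment against 7.68 and 14.3 in control.

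The other fixed lists had intervals that included 0. Median log2 ratios were -0.04 for glycolysis (percentile 57.9), -0.04 for the NRF2 antioxidant list (percentile 46.5), -0.03 for axon cytoskeleton and transport (percentile 60.005) and 0.14 for pacemaking and ion channels (percentile 97.7). They were 0.07 for p53 and apoptosis (percentile 76.9), 0.28 for the axon injury response (percentile 98.0) and -0.17 for interferon and class I genes (percentile 35.2). With equal weights the axon injury response had a median of 0.10 (percentile 81.9) and pacemaking and ion channels 0.04 (percentile 78.4). The axon injury median was -0.43 in title set 1 and 0.82 in title set 2, and the pacemaking median 0.03 and -0.26. Some members stood apart. The metallothioneins Mt1 and Mt2 had ratios of 2.63 and 4.26 and the ferritin heavy chain Fth1 1.90, while Gclc, which makes a glutathione precursor, had 0.430. Experiment library 27 held 35.4% of the Mt1 counts and 44.6% of the Mt2 counts of its group. Without the highest library of each group the ratios of Mt1 and Mt2 were 1.86 and 2.54. Mt2 was above the control median in 19 of 38 experiment libraries. The neurofilament genes Nefm and Nefl had ratios of 1.79 and 1.61. The calcium channel genes Cacna1g and Cacna1a had 0.375 and 0.414, and the injury-associated transcription factors Jun and Klf6 1.82 and 1.73.

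**Figure D3:**
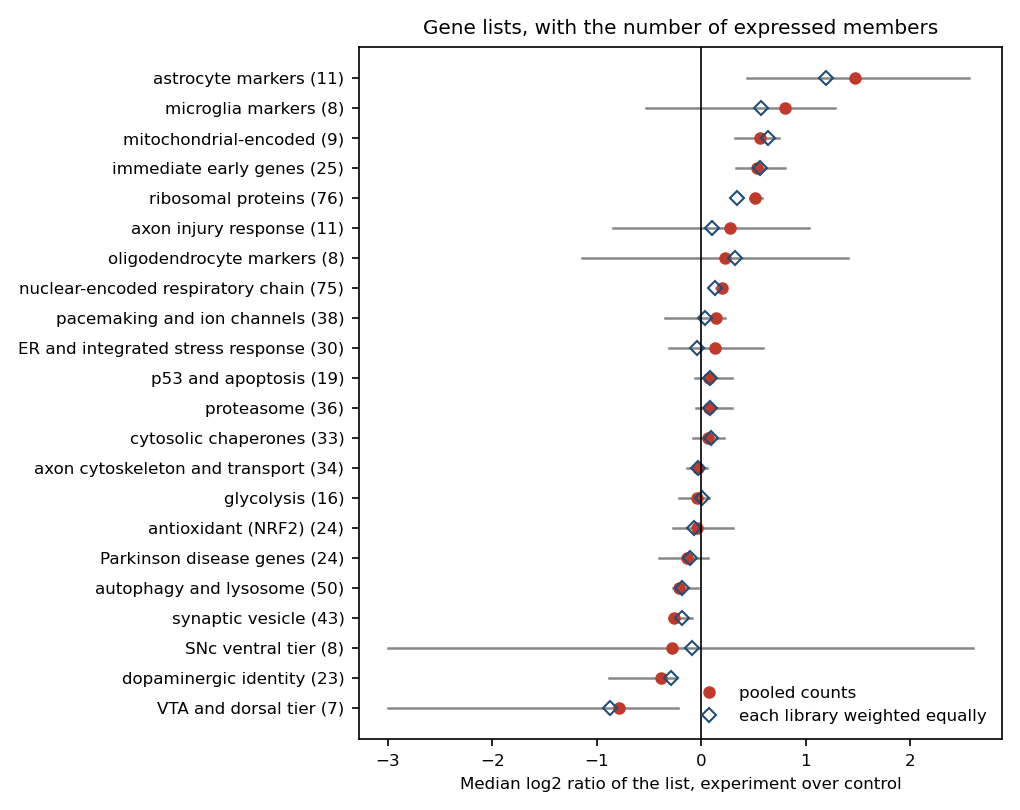
Median log2 ratio (experiment over control) of each list fixed in advance that had at least 6 expressed genes, from pooled counts (filled circles) and with each library weighted equally (open diamonds). Grey lines are 95% intervals over the genes of the list, and the number of expressed genes is in brackets. Astrocyte markers have the highest pooled median (1.47) and the ventral tegmental and dorsal-tier list the lowest (-0.79).

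By the fixed rule of size, the genes furthest above control included Ccnd1, a G1 cyclin, at 38.8 against 2.62 CPM, the endothelin receptor gene Ednrb at 43.1 against 3.71 CPM, and Gata3 at 31.9 against 3.75 CPM. Agt, Psat1, Gja1, Crym, Anxa1, Phgdh, Naif1, Gpr37l1 and Msantd1 followed, with ratios from 4.80 to 6.50. The ratio of Ccnd1 was 14.8, and 9.44 without experiment library 4, which held 52.9% of its counts, and the highest control library. Within title sets 1 and 2 it was 12.8 and 8.21. The ratio of Crym was 5.84 pooled, and 4.46 and 2.04 within the sets. The genes furthest below control were Proser2, Igfbp4, Gdpd2 and Cacng5, with 12, 33, 20 and 5 counts in all experiment libraries against 1451, 1764, 1445 and 1587 in control. Chat, the acetylcholine-synthesising enzyme, stood at 1.29 against 15.8 CPM, and Ngb, neuroglobin, at 2.61 against 29.8 CPM. Magel2, Pip5kl1, Rtel1, R3hcc1l, Unc13c and Atg9b followed, with ratios from 0.081 to 0.120.

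Most of these extreme genes were found in a minority of libraries, and Crym, Msantd1 and Naif1 were lower among libraries with genes detected at or above the overall median, a split chosen after seeing the data (log2 ratios -3.09, -0.73 and -0.95). After thinning, Ccnd1 had a count in 13 of 34 experiment and 15 of 60 control libraries, and Proser2 in 1 and 20. A single library held all the experiment counts of Proser2 (experiment 52) and Cacng5 (experiment 35), 97.0% of those of Igfbp4 (experiment 21), 95.1% of Atg9b (experiment 40), 78.8% of Chat (experiment 37) and 72.9% of R3hcc1l (experiment 26). Without the highest library of each group, the ratios of Chat and R3hcc1l were 0.021 and 0.028, and 4 or fewer experiment counts were left for the others named here. The ratio of Magel2 was 0.055 without its highest libraries, among them experiment library 34. In libraries simulated with the control spread and no difference, 30.5% of the 1519 genes found in under 50% of libraries still passed 1.5-fold by both weightings, against 0.875% of the 2629 genes found in at least 90%. The simulated libraries were independent of each other, without title sets, animals or differences in yield, so these shares may be too low for the real libraries.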

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

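The tests of low RNA yield and of GABAergic RNA in this part, and the use of the glial setting as a test, were chosen after the results were seen, while leaving out the libraries highest in glial markers was an alternative fixed in advance. Spike-in RNA, which entered no comparison of genes, took a larger share of the experiment libraries. The median ERCC share was 0.421% in experiment and 0.251% in control libraries, and this came with fewer genes detected at equal depth (median 6916 against 8460). If the same amount of spike-in was added to every tube, which the labels do not state in numbers, the experiment pipettes delivered less RNA.

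The lower dopaminergic transcripts are a pattern on which this bears. The 12 experiment and 40 control libraries with an ERCC share at or below the overall median gave the dopaminergic list a median log2 ratio of -0.65. Its interval over genes was -0.82 to -0.33, and the median of all libraries was -0.38. The difference was thus not confined to libraries high in spike-ins. Experiments 2 and 21, the deepest of the 12, weigh most in pooled counts. Their dopaminergic CPM were 12789 and 5890 (group median 19351), while experiments 23, 25, 33, 35, 44 and 48 lay above that median. The split therefore also changes cell content, and low yield stays open. Without the libraries highest in glial markers the median was -0.23 (-0.71 to -0.13), so those libraries may account for part of the difference but not all of it. Astrocyte markers were still higher without them (median 0.29), so glial RNA in the other libraries stays open. Experiment libraries 27, 49, 52 and 5 had the lowest summed dopaminergic CPM of their group (1119, 4178, 4695 and 5351, against a median of 19351). Their GABAergic marker CPM were 1055, 2012, 1253 and 1083 (median 342), and their glial marker CPM 16921, 8469, 17262 and 4170 (median 2222). Controls 5 and 7 had dopaminergic CPM of 3172 and 5189 (median 26372) and GABAergic CPM of 980 and 1517 (median 255). Their glial CPM were 4072 and 5569 (median 1210). Without the 7 experiment and 4 control libraries above the 90th percentile of GABAergic marker CPM, the dopaminergic median was -0.33 (-0.61 to -0.09) and Th stood at 6058 against 10014 CPM, which argues against those libraries as the whole source. Experiment 27 and control 5 were not among them, and GABAergic markers were still higher (0.74, range -0.29 to 1.28), so RNA of GABAergic neurons in the other libraries stays open. Th stood at 4833 against 9222 CPM in the libraries low in spike-ins. These intervals span genes and not animals, and a difference between animals, or in how neurons of each group were chosen within the nigra, stays open, as does an effect of the inclusions, which the labels do not allow to be tested.

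The mitochondrial-encoded list, with a median of 0.56 over the full set of libraries (interval 0.32 to 0.74), stood at 0.16 in the libraries low in spike-ins, below that interval. Experiment 2, the deepest library of its group (3094036 gene counts), is among the libraries low in spike-ins. It had the lowest mitochondrial share of the group (0.495%). Experiments 5, 13 and 21 of the same split, like experiment 2 in title set 1, had 1.09%, 1.31% and 1.38% (group median 4.33%). Experiments 23, 25, 33 and 44 of the split lay above that median. Low yield, the weight of the libraries with low shares and their title set were not told apart as sources of the shift, which stays open.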

How the results depend on the processing

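No paired analysis was possible because the results come from no test and shared title numbers do not tie experiment to control libraries. Settings that use spike-in share, genes detected, the highest library per gene, GABAergic markers or controls 38 and 53 were chosen after seeing the data. The library filter and the requirement of dopaminergic markers left out 0 libraries, so they say nothing about stability. TMM factors, totals without mitochondrial and top genes, both expression filters, the stricter library filter, leaving out the deepest libraries, and counting controls 38 and 53 once moved no list median beyond its interval, although the stricter expression filter left 3 lists without a value. Values below are median log2 ratios, and the cause of each shift was not tested. With mean log2(CPM + 1), the scale on which all genes shift by -0.38, the stress list was -0.38, lysosome -0.29, respiratory chain 0.090, ribosomal 0.26 and synaptic vesicle -0.31. With equal weights the respiratory chain was 0.13 and ribosomal 0.34. In title set 1 (all genes -0.10) the dopaminergic list was -0.20, lysosome -0.032, ribosomal 0.40 and microglia 2.28. In title set 2 the respiratory chain was 0.12, ribosomal 0.66, synaptic vesicle -0.37 and oligodendrocyte -2.17. Without libraries high in glial markers the dopaminergic list was -0.23, ribosomal 0.58 and astrocyte 0.29. Without libraries high in GABAergic markers the respiratory chain was 0.12 and ribosomal 0.59. In libraries low in spike-ins, 12 experiment and 40 control, lysosome was -0.39, respiratory chain 0.34, ribosomal 0.82, mitochondrial 0.16, synaptic vesicle -0.31 and astrocyte -0.27, a reversal. In libraries with more genes detected, 13 and 39 (all genes -0.12), chaperones were -0.12, ribosomal 0.91, synaptic vesicle -0.47 and astrocyte 2.79. Without the highest library per gene (all genes -0.16) the respiratory chain was 0.14, ribosomal 0.41 and synaptic vesicle -0.32. Counting the ribosomal and mitochondrial lists and those not named above, 30 medians of 11 lists moved beyond their intervals, and 7 of these crossed 0, in the glycolysis, ion channel, p53 and interferon lists, whose intervals held 0. Genes named outside the full rule changed sign in title set 1 in 9 cases and in title set 2 in 11, among them Foxa2, Aldh1a1, Cryab, Cd63, Adcyap1 and Neurod6, and in fewer cases under other settings. Genes that met the full rule, which asks for a common direction in both title sets, reversed as follows. In libraries low in spike-ins log2 ratios were -0.57 for Agt, -0.063 for Ctss, -0.36 for Fcer1g, -1.17 for Gja1, -1.12 for Gjb6, -0.18 for Npc1, -0.078 for Ntsr2 and -0.66 for Tars. Without libraries high in glial markers Gja1 was -0.26. In libraries with more genes detected Crym was -3.09, Msantd1 -0.73 and Naif1 -0.95. Depth limits genes found in few libraries, whose ratios moved with the libraries included.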

Other observations

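The 4 gene lists in this part, the widely detected genes and the tests in libraries low in spike-ins were chosen after the results were seen. The tests of astrocyte RNA and of transcript length address patterns that had also been seen, and were chosen before their own values were seen. Within the fixed stress list, genes that the transcription factor ATF4 induces stood apart from chaperones of the endoplasmic reticulum. All 11 expressed genes of the ATF4 branch were higher by both weightings, with a median log2 ratio of 1.27 (0.59 to 2.43). Slc3a2, the heavy chain of amino acid transporters, stood at 387 against 171 CPM, Ddit3, a stress transcription factor also called CHOP, at 188 against 78.2 CPM, and Asns, asparagine synthetase, at 548 against 308 CPM. Each of Slc3a2 and Ddit3 was above the control median in 29 of 38 experiment libraries. The chaperone branch had a median of -0.31 (-0.49 to 0.10), with 14 of 19 genes lower, among them Pdia6 (ratio 0.682), Calr (0.714) and Canx (0.757), while Hspa5 was nearly level (0.961). Cytosolic aminoacyl-tRNA synthetases, many of which ATF4 also induces, had 13 of 20 genes higher and 4 lower, with a median of 0.39 (-0.08 to 0.80). Cars, Aars, Sars and Gars had ratios of 2.31, 1.87, 1.74 and 1.74, and Wars 0.618.

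Cholesterol synthesis genes were lower. Of 19 expressed genes, 15 were lower and 1 higher by both weightings, with a median of -0.74 (-0.84 to -0.06) and percentile 0 among 10000 random lists, which, as for the other lists here, were drawn after the members had been seen. Hmgcs1, an early enzyme of the pathway, had a ratio of 0.567 and lay below the control median in 33 of 38 experiment libraries, and Sqle, squalene epoxidase, had 0.558 and lay below it in 31. The median was -0.62 in title set 1 and -0.55 in title set 2.

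Genes found in at least 80% of thinned libraries of both groups numbered 2731. Among those that moved the same way in both title sets, ranked by the smaller of the pooled and equally weighted log2 ratios, Apoe, the lipid carrier of glia, was highest at 741 against 226 CPM. Experiment library 27 held 38.9% of its experiment counts, and its ratio of 3.28 was 2.60 without the highest library of each group. After thinning, Apoe had a count in 29 of 34 experiment and 53 of 60 control libraries. Nrgn, a calmodulin-binding synaptic protein, had a ratio of 2.39, Ybx1, an RNA-binding protein, 2.25, and Lmo3, a transcriptional regulator of the LIM family, 2.12. The ratio of Nrgn was 2.23 in title set 1 and 1.25 in title set 2, both below the pooled value. Those of Ybx1 were 2.26 and 2.40, and those of Lmo3 1.31 and 3.18. Ybx1 was above the control median in 33 of 38 experiment libraries. The lowest by the same ranking were Serpini1, neuroserpin, at 118 against 268 CPM, and Dlk1. Kcnip4, a potassium channel partner, had a ratio of 0.483, Chl1, a cell adhesion molecule, 0.517, and Ptprn, a dense-core vesicle protein, 0.537.

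For the higher ATF4-branch genes, RNA of astrocytes was a candidate source, since astrocytes express Psat1 and Phgdh strongly and astrocyte markers were higher. Among the 15 experiment and 37 control libraries with astrocyte marker CPM at or below the overall median, the list had a median of 1.55 (0.64 to 3.16). Psat1 stood at 233 against 25.98 CPM there, which argues against astrocyte RNA as the whole source. The split did not hold the title sets apart, and the list differed between them. In the libraries low in spike-ins the median was 0.82 (0.38 to 1.87), with Phgdh at 24.1 against 18.4 CPM. The difference remained there and was smaller, and the part of low RNA yield in it is not settled. The median was 0.42 in title set 1 and 1.59 in title set 2, and Atf4 itself had log2 ratios of -0.42 and 1.25, so the size of the pattern differed between sets by an amount that was not tested. Amino acid or integrated stress in the experiment neurons is a hypothesis that these libraries leave open, as is a difference in slice handling between groups.

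For the higher ribosomal protein and respiratory chain genes, a preference for short transcripts may be proposed, because their median lengths were 942 and 908 bases against 3299 for expressed genes. Random lists matched on both expression and transcript length had medians of 0.068 and 0.046, against 0.52 and 0.20 for the lists, which argues against length as the whole cause. Length had a weak relation to the ratio across genes, with a median of 0.07 in the shortest of 5 equal groups and -0.11 in the longest. The ribosomal median was 0.82 (0.73 to 0.96) in libraries low in spike-ins, so the difference was not confined to libraries high in them. Experiments 2 and 21, the deepest experiment libraries of that split, weigh most in it, so the part of low yield is not settled. Reads shared with pseudogenes and a difference between cells remain open.

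By correlation, controls 38 and 53 resembled each other more than any other pair of libraries. Their count differences, scaled to sampling noise as a chi-square per degree of freedom, stood at 14.3. The lowest value over all pairs was 7.80. For counts that vary beyond sampling noise this measure grows with depth, so it does not rank pairs of unlike depth by closeness. The pairs next in correlation stood at 26.7 to 42.8. Over expressed genes, the log2(CPM + 1) values of controls 38 and 53 had a Pearson correlation of 0.824. The next pair had 0.659, and the median over all pairs was 0.449. Of the 2155 genes above 100 CPM in control 38, 0 were absent from control 53, and the same held for the 2171 genes in the other direction, against a median of 220 absent genes over ordered pairs. Of 57 genes above 10 CPM in control 38 that had a count in at most 5 libraries, 30 had a count in control 53 and at most 6 in any other library. The 2 libraries may share RNA or cDNA, in which case the control libraries stand for fewer neurons than their number, and the counts do not settle this. Both were kept. With control 53 left out, a setting added after seeing the data, the dopaminergic list had a median of -0.37.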
